A study of Rattus norvegicus with 36 samples.

How the data were processed

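Total RNA sequencing of thoracic descending aorta from male rats was analysed. The labels give 36 samples in 6 groups of 6, from 3 strains on 2 diets. The strains were the Dahl salt-sensitive rat (SS) and 2 congenic strains on that background, which carry a Brown Norway (BN) piece of chromosome 2, either its distal portion (S2Ba) or a middle segment (S2Bb). Per the labels' protocols the animals were 4 to 6 weeks old at the start, received a normal salt diet or a high salt diet with 4% NaCl and were kept on it until they were 12 to 13 weeks old. Values were held for 34 libraries, and SS high salt replicate 3 and S2Ba high salt replicate 2 were not analysed here. Replicate numbers follow the order of the records and pair no samples across groups. The labels do not say in words that each sample is a separate animal, so the p-values measure the spread between these samples.

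Per the submitters' processing notes, bcl2fastq 1.8.4, FastQC, STAR 2.3.1, R 3.2.3 and edgeR 3.6.8 were used. The roles and settings of these tools, the genome build, the annotation and the counter are not given in the sources used here, nor is whether reads were counted by strand. The deposited table holds 1 signal value per gene and library. The values the authors deposited were not counts: in every library they were whole multiples of a single step, which was the value of 1 read, between 0.0659 and 0.12 depending on the library. With a tolerance of 0.01 reads, 100% of the values came out as whole reads, so the signal is a read count divided by a size factor of its library. Values summed to between 947769.7 and 1181335 per library. Recovered depth was 8753735 to 15168833 reads per library. The authors' table was used for all 26106 genes it lists, and no value column was left unused. Of these genes, 29 have no symbol and took at most 0.01953% of the reads of a library, and 270 symbols occur more than once. In the most concentrated library 22.52% of the reads fell in the most abundant gene (13.94% in the least), which was AY172581.24 in every library. Mitochondrial genes with a symbol starting with Mt- took 1.183% to 3.011%. Mitochondrial transcripts under other symbols are not in that share, so it is not the whole mitochondrial share.

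Counts had been foreseen, with the edgeR quasi-likelihood test. Because the deposited signal is normalised, the test foreseen for normalised values was used instead: limma 3.58.1 with an intensity trend in R 4.3.3 on log2(value + 0.5), for the 13475 genes with a mean value of at least 0.5 over the 34 libraries. The other 12631 genes were not tested. A model with 1 mean per group was fitted to all 6 groups, which share the estimate of the spread, and 9 contrasts were taken: high against normal salt in each strain, each congenic strain against SS on each diet, and the difference in the salt response between each congenic strain and SS (interaction). P-values were 2-sided and adjusted by the Benjamini-Hochberg method over the tested genes of a contrast, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(value + 0.5) scale, which understates the change of genes with low values. Where a group held 0 reads of a gene, the ratio was taken against a floor of 3 counts over the whole group, which covers counting error only.

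The choices of test, gene lists and named genes were made before the data were examined. The filter on the mean value was not fixed in advance, and counts depend on it. With no filter the count for salt in SS went from 1129 to 723, and that of the S2Bb interaction from 23 to 1. The genes named for a contrast were the 8 called genes with the smallest adjusted p in each direction that had an informative symbol and a mean of at least 1, up to 4 called members of each list, Enpep and Hs2st1 in every strain contrast, and, for strain contrasts, the 5 called chromosome 2 genes with the largest fold change and a mean of at least 1. The rule was written for 36 libraries and applied to 34. Enpep and Hs2st1 were taken because the study itself singled them out from these samples, so they are not independent evidence. A few other genes are named, and are then said to have been chosen after their values were seen.

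Gene lists were tested with camera in limma with a preset correlation of 0.01, and again with a correlation estimated from the data. The 28 lists were renin-angiotensin and endothelin, heparan sulfate synthesis, inflammatory mediators and adhesion, extracellular matrix, smooth muscle contractile genes, oxidant and antioxidant genes, sodium transport and mineralocorticoid genes, potassium and calcium channels, oxidative phosphorylation, circadian clock, immediate early genes, glucocorticoid response, cell cycle, interferon response, antigen presentation and fatty acid synthesis, and markers of endothelial cells, macrophages, T and NK cells, B and plasma cells, mast cells, adipocytes, skeletal muscle, cardiac muscle, erythroid cells, Schwann and neuronal cells, mesothelium and chondrocytes. Cma1, Kcnmb1 and Lcn2 each stand in more than 1 list. For 13 of the marker lists, the mean log2(value + 0.5) of the members was compared between groups with an exact permutation test in 7 contrasts, and the 91 p-values were adjusted within each contrast. Chromosomes and the order of genes along them came from a RefSeq gene table of the assembly GRCr8, matched by symbol or synonym. This table placed 12239 of the tested genes, 816 of them on chromosome 2. No coordinates were used because the build of the files is not given in the sources used here. Enrichment of chromosome 2 among called genes was tested with Fisher's exact test.

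Contrasts that share SS libraries were compared with 100 simulations of unchanged groups, and with the SS libraries split between the strains. Each pair of replicates was compared by a chi-square per gene, which ran from 7.265 to 57.91 over the 80 pairs within groups, so no library was present more than once in a group. Pairs across groups were not compared. For each count of called genes, 100 splits of the samples into groups of the real sizes were counted, the real one included. The alternatives were other scalings of the recovered reads (relative log expression and upper quartile, put into the same limma model), DESeq2 1.42.0, limma voom with sample quality weights, no filter or a mean of at least 1, a fit of the compared groups alone, surrogate variables from sva 3.50.0 (at most 3), adipocyte and skeletal muscle scores as covariates, pseudocounts of 0.1 and 1, and stricter thresholds. The edgeR 4.0.16 quasi-likelihood test on the recovered reads, the omission of each library in turn, the omission of SS normal salt replicates 1 and 2 or of S2Ba normal salt replicate 1, and the first 2 principal components of the clock list as covariates were added after the data were seen.

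The test was checked on simulated counts for the 13475 genes. For salt in SS it recovered 35 of 67 genes changed 1.5-fold, 53 of 67 changed 2-fold and 63 of 66 changed 3-fold, with 14 false calls. For S2Ba against SS on normal salt it recovered 31 of 67, 54 of 67 and 63 of 66, with 5 false calls. For the S2Bb interaction it recovered 168 of 200 genes changed 3-fold, with 6 false calls. The counts were drawn for each gene independently, without differences between libraries that move many genes together. The numbers of false calls therefore do not cover such differences in the real libraries.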

Results

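RNA of the thoracic descending aorta was sequenced from male salt-sensitive SS rats and from congenic rats that carry BN sequence in the distal (S2Ba) or middle (S2Bb) part of chromosome 2, each on normal or high salt. Library numbers were 6 for SS on normal salt, 5 for SS on high salt, 6 and 5 for S2Ba, and 6 and 6 for S2Bb. Recovered depth was 8753735 to 13398098 reads for SS on normal salt and 11667349 to 13483126 on high salt, 10315509 to 14408310 and 11106259 to 13004721 for S2Ba, and 12206970 to 15168833 and 9882071 to 12597756 for S2Bb. Values are normalised read values, reads scaled to a common library size and given as mean ± SD. The series asks which genes respond to salt in the vessel wall of these strains, and which differ between strains that carry different parts of chromosome 2. In the labels the work is set in the context of vascular inflammation.

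On high salt, Slc6a6, the taurine transporter, rose in SS rats from 48.7 ± 8.40 (n = 6) to 109.9 ± 15.6 (n = 5), a log2 fold change of 1.17 (SE 0.16), and Atp1b1, a subunit of the sodium-potassium pump, rose from 56.3 ± 8.75 to 118 ± 19.9. Postn, which encodes the matrix protein periostin, rose from 487 ± 237 to 1092.5 ± 125. Deptor, which binds and inhibits mTOR, fell from 29.2 ± 4.26 to 15.6 ± 1.83, and Dapk1, a death-associated kinase, fell from 33.1 ± 7.01 to 11.7 ± 6.17. Kdr, the main VEGF receptor of endothelium, fell from 16.1 ± 5.67 to 5.44 ± 1.60. In limma with Benjamini-Hochberg adjustment the adjusted p was 7.92e-05 for Slc6a6, 0.00146 for Atp1b1, 0.0167 for Postn, 2.66e-05 for Deptor, 0.000283 for Dapk1 and 0.00559 for Kdr. For 5 of these 6 genes no high salt library overlapped the normal salt libraries, and the exception was Dapk1. Chance gives such a separation for 0.433% of genes, but the genes named here and below were mostly taken for a small adjusted p, so it was to be expected of them and is no further evidence. The call of Kdr was lost with surrogate variables as covariates (adjusted p = 0.0579), and that of Postn without SS normal salt replicate 6 (adjusted p = 0.0553).

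Of all tested genes 8.38% were called for salt in SS rats, against which the counts of the lists are to be read. Of 24 measured cell cycle genes, 15 rose and 0 fell in SS rats, and 18 were called when adjusted over the list alone. Mki67, a marker of proliferating cells, rose from 9.66 ± 3.70 to 22.8 ± 2.98, Mcm5, a subunit of the replicative helicase, from 1.95 ± 0.846 to 6.04 ± 2.77, and Kif20a, a mitotic kinesin, from 2.37 ± 1.499 to 9.04 ± 2.69. The list passed camera at an adjusted p of 6.21e-13, with an adjusted p = 0.599 with an estimated correlation. Of 18 genes of sodium transport, 4 rose and 0 fell, with 8 adjusted over the list alone (camera adjusted p = 0.0576). Of 25 potassium and calcium channel genes 2 rose and 3 fell, with 6 adjusted over the list alone, and Cacna1h, a T-type calcium channel, fell from 13.4 ± 1.97 to 7.28 ± 2.12. Of 20 contractile genes of smooth muscle 2 rose and 1 fell, with 8 adjusted over the list alone (camera adjusted p = 0.0489, and adjusted p = 0.863 with an estimated correlation). Pln, the inhibitor of the calcium pump of the sarcoplasmic reticulum, rose from 310 ± 89.8 to 535 ± 80.2. Of 16 endothelial genes 0 rose and 2 fell, with 5 adjusted over the list alone (camera adjusted p = 0.00688, and adjusted p = 0.847 with an estimated correlation). Calls of Mki67 and Kif20a were lost with surrogate variables (adjusted p = 0.0893 and 0.0707), and that of Pln with clock components as covariates (adjusted p = 0.0571).

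Clock genes differed between diets in SS rats and also between animals on high salt. Of 17 clock genes 7 rose and 4 fell, with 13 adjusted over the list alone. Arntl, the activator at the core of the clock, fell from 77.6 ± 9.11 to 19.8 ± 30.7, a log2 fold change of -3.001 with an adjusted p of 0.00643 in limma. Across the SS high salt libraries Arntl ran from 2.43 to 74.3, against 60.1 to 87.2 on normal salt. Dbp, a clock output gene, stood at 132 ± 83.4 on high salt, with a range of 5.28 to 210.1, and at 8.27 ± 2.83 on normal salt. The call of Arntl was lost in edgeR (adjusted p = 0.0561) and with the clock components as covariates (adjusted p = 0.329), which takes out much of its change by construction because Arntl is a member of the list they come from.

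Altogether limma called 1129 genes for salt in SS, of which 598 were higher and 531 lower, and 189 differed at least 2-fold. The direction with more calls turned among genes changed at least 1.5-fold, with 232 higher and 329 lower. With the first 2 clock components as covariates the count was 510. Without SS normal salt replicate 3, 4, 5 or 6 it was 1709, 722, 681 or 525, and without SS high salt replicate 2, 4, 5 or 6 it was 708, 556, 519 or 550.

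In S2Ba rats Sost, which encodes the Wnt antagonist sclerostin, rose on high salt from 2.18 ± 0.606 (n = 6) to 33.6 ± 19.3 (n = 5), 11.6-fold on the fitted scale, and Ano1, a calcium-activated chloride channel of smooth muscle, rose from 116 ± 22.1 to 420.5 ± 126. Enpep, the aminopeptidase that shortens angiotensin II, rose from 16.01 ± 4.40 to 54.3 ± 19.03, and Edn1, the precursor of the vasoconstrictor endothelin-1, rose from 2.33 ± 0.959 to 9.06 ± 3.39. Postn rose from 533 ± 245 to 2708 ± 840. Plppr4, a lipid phosphatase-related membrane protein, fell from 3.64 ± 0.694 to 0.319 ± 0.278, and Fam132a, a secreted protein of the adipokine type, fell from 14.7 ± 10.7 to 1.66 ± 0.780. The adjusted p from limma was 1.33e-06 for Sost, 5.33e-06 for Ano1, 1.6e-05 for Enpep, 0.000104 for Edn1, 2.36e-05 for Postn, 1.13e-06 for Plppr4 and 1.6e-05 for Fam132a. All 5 high salt libraries lay outside the range of the 6 normal salt libraries for each of these 7 genes (0.433% for a gene not chosen for its difference).

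All 21 of the called cell cycle genes rose in S2Ba rats, out of 24 measured, and all 24 were called when adjusted over the list alone (camera adjusted p = 4.83e-16, and adjusted p = 0.294 with an estimated correlation). Of 40 genes of the extracellular matrix 7 rose and 5 fell, with 15 adjusted over the list alone. Fn1, which encodes fibronectin, rose from 1253 ± 388 to 3825 ± 2258, Spp1, which encodes osteopontin, from 931 ± 137 to 2648 ± 1279, and Timp1, an inhibitor of matrix metalloproteinases, from 42.1 ± 8.22 to 77.8 ± 19.1. Of 18 sodium transport genes 7 rose and 2 fell, with 9 adjusted over the list alone. Of 16 renin-angiotensin and endothelin genes 2 rose and 3 fell, with 8 adjusted over the list alone. Enpep stands in this list and was picked by the study on these samples, so its count is not independent evidence. Ednra, the endothelin receptor of smooth muscle, fell from 51.3 ± 13.3 to 31.6 ± 3.76. Of 25 inflammatory mediators and adhesion genes 4 rose and 1 fell, with 5 adjusted over the list alone. Vcam1, an adhesion molecule for leukocytes, rose from 178 ± 47.8 to 281 ± 46.9, a call that was lost with surrogate variables (adjusted p = 0.0528). Of 19 macrophage genes 2 rose and 0 fell, with 2 adjusted over the list alone (camera adjusted p = 0.000395, and adjusted p = 0.913 with an estimated correlation). Of all tested genes 15.2% were called for salt in S2Ba. The number of called macrophage genes does not stand out from that share, and that of inflammatory genes lies near it. The mean macrophage score was 4.53 ± 0.444 on high salt and 4.09 ± 0.246 on normal salt (adjusted p = 0.169, exact permutation test).

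For salt in S2Ba, limma called 2042 genes, 1094 higher and 948 lower, of which 393 differed at least 2-fold. The direction with more calls depended on the setting. The count was 1093 when only the S2Ba libraries were fitted and 923 with surrogate variables. Leaving out 1 library at a time moved it between 1508 and 2409.

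In S2Bb rats Tnnc1, the troponin C of slow and cardiac muscle, rose on high salt from 0.573 ± 0.229 to 21 ± 15.2 (n = 6 each), and Kcnq3, a voltage-gated potassium channel, rose from 0.276 ± 0.254 to 5.35 ± 1.90. Cacna1d, an L-type calcium channel, rose from 0.565 ± 0.268 to 11.6 ± 4.16, and Casq2, a calcium-binding protein of the sarcoplasmic reticulum, from 160 ± 31.4 to 385 ± 109. Slc6a6 rose from 31.4 ± 3.85 to 95.1 ± 12.9, Sost from 0.617 ± 0.549 to 14.9 ± 5.82 and Postn from 504 ± 207 to 2114 ± 1053. Plppr4 fell from 5.91 ± 1.89 to 0.744 ± 0.471, and Blk, a kinase of B cells, fell from 2.63 ± 0.986 to 0.231 ± 0.159. The log2 fold change was 4.11 for Tnnc1 (SE 0.44), 2.92 for Kcnq3 (SE 0.28), 3.46 for Cacna1d (SE 0.41) and -2.39 for Plppr4 (SE 0.25), with adjusted p of 1.66e-07, 2.94e-08, 6.26e-07 and 1.15e-07 in limma. Kcnq3 had 0 reads in 2 normal salt libraries. None of the 6 high salt libraries overlapped the normal salt libraries for these 9 genes (0.216% for a gene not chosen for its difference).

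Of 24 cell cycle genes 22 rose and 0 fell in S2Bb rats, with 23 adjusted over the list alone (camera adjusted p = 1.26e-16, and adjusted p = 0.35 with an estimated correlation), and Mki67 rose from 7.23 ± 2.76 to 33.9 ± 8.61. Of 25 potassium and calcium channel genes 6 rose and 9 fell, with 16 adjusted over the list alone. Among 20 contractile genes of smooth muscle 5 rose and 3 fell, with 10 adjusted over the list alone, and Pln rose from 189 ± 26.3 to 623 ± 169.6. Of 40 matrix genes 5 rose and 9 fell, with 15 adjusted over the list alone, and Timp1 rose from 31.6 ± 1.87 to 65.8 ± 23.6. Of 18 sodium transport genes 6 rose and 2 fell, with 10 adjusted over the list alone, and of 15 glucocorticoid response genes 5 rose and 1 fell, with 6 adjusted over the list alone. Of 24 oxidant and antioxidant genes 1 rose and 6 fell, with 7 adjusted over the list alone. The member that rose was Nox4, a superoxide and peroxide producing oxidase, from 52.0 ± 23.2 to 118 ± 26.1. In the renin-angiotensin and endothelin list 2 of 16 rose and 3 fell, with 5 adjusted over the list alone, and Agtr2, the type 2 receptor of angiotensin II, fell from 5.04 ± 1.199 to 1.08 ± 0.787. Of 25 inflammatory mediators and adhesion genes 5 rose and 1 fell, with 6 adjusted over the list alone. Of 19 macrophage genes 3 rose and 0 fell, with 3 adjusted over the list alone (camera adjusted p = 0.0412, and adjusted p = 0.982 with an estimated correlation). Of all tested genes 22.1% were called for salt in S2Bb, and the numbers of called inflammatory and macrophage genes do not stand out from that share. As 4658 of 13475 genes had an unadjusted p under 0.05, a count adjusted over a list alone does not show that the list stands out. The marker score of mesothelium (1.96 ± 0.164 to 1.24 ± 0.329, 3 measured genes) was lower on high salt with an adjusted p of 0.014 (exact permutation test), through Krt18 (log2 fold change -1.82) and Krt8 (-0.55) and not Msln (0.22). That of B and plasma cells (1.22 ± 0.219 to 0.201 ± 0.246, adjusted p = 0.014) has 2 measured genes and rests on Blk alone, as Cd22 stood at 0.02.

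For salt in S2Bb, limma called 2974 genes, 1438 higher and 1536 lower, of which 434 differed at least 2-fold. Neither direction prevailed across settings, with 1610 higher and 1379 lower under upper quartile scaling and 1688 and 1626 in DESeq2. With the clock components as covariates the count was 1458. Leaving out 1 library at a time moved it between 2420 and 3022.

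**Figure D1:**
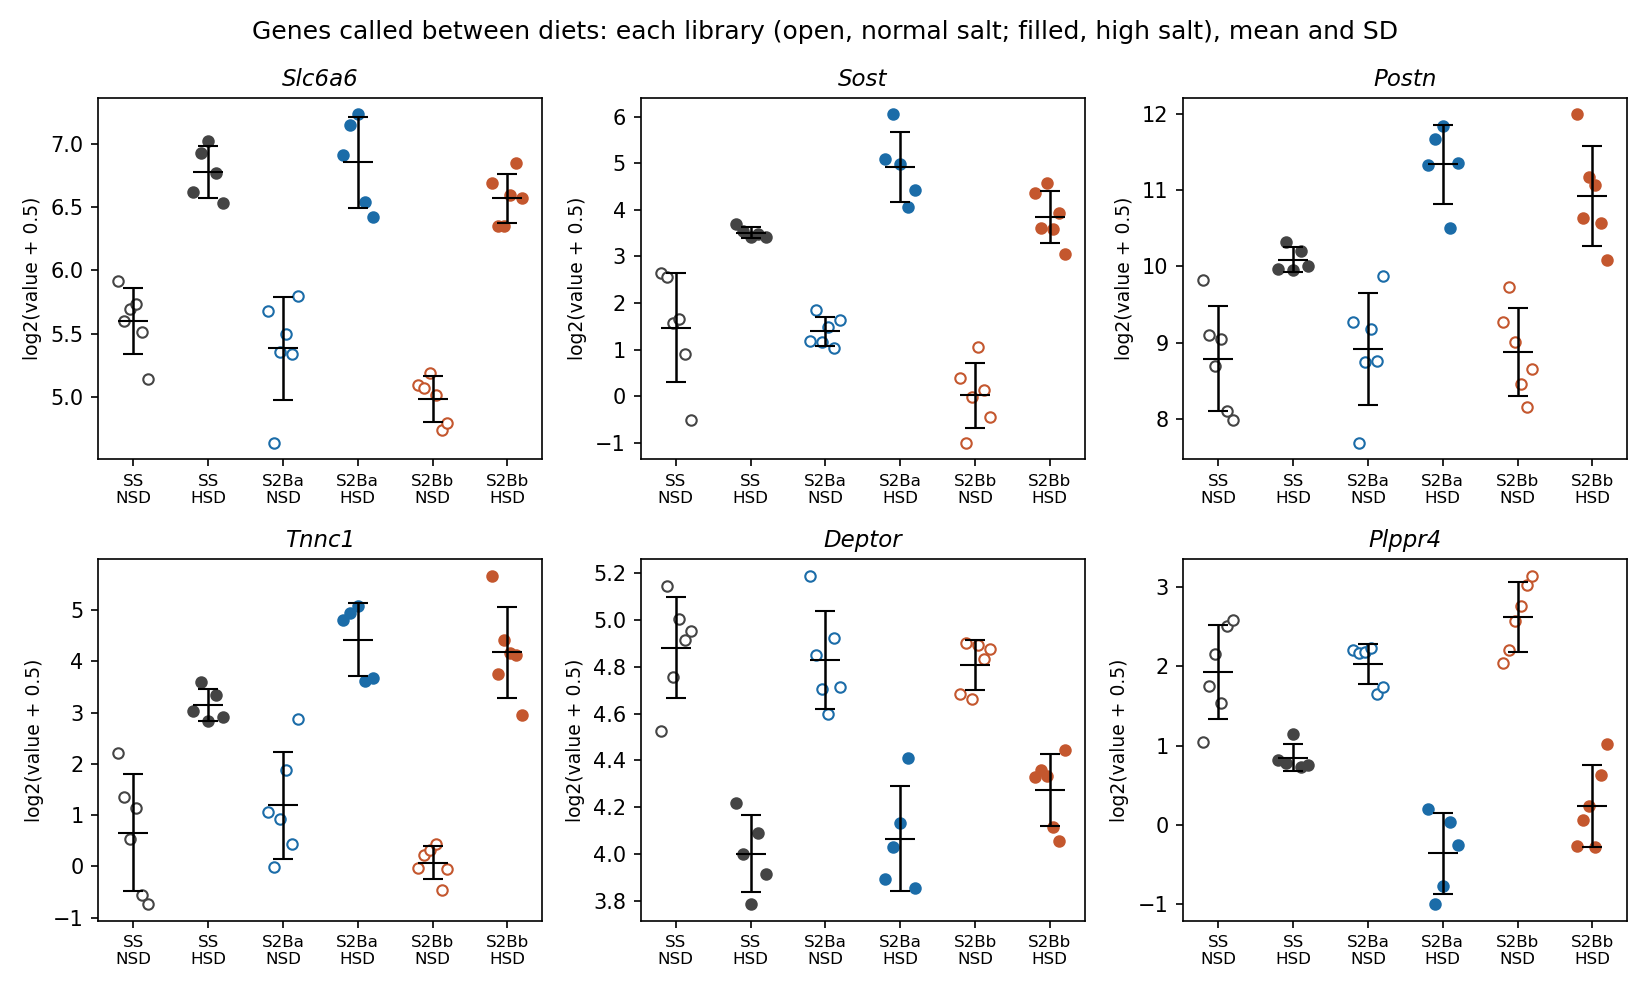
Each library's log2(value + 0.5) for 6 genes called between diets (vertical axes, 1 panel per gene), by strain and diet (horizontal axes, NSD normal salt and HSD high salt), with open points for normal salt, filled points for high salt, and bars for the mean and SD. Slc6a6, Sost, Postn and Tnnc1 lie higher and Deptor and Plppr4 lower on high salt in each strain.

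The salt responses of the strains were compared gene by gene. In limma 450 genes were called in all 3 strains with the same direction, 278 higher and 172 lower, against 5.18 and 4.26 for independent lists, and 7 genes were called in opposite directions in at least a pair of strains among the 4155 called in any. Slc6a6, Atp1b1, Sost, Postn and Mki67 rose and Deptor fell in each strain. Across genes, which are not independent replicates, the log2 fold changes for salt correlated at 0.639 between SS and S2Ba, 0.614 between SS and S2Bb and 0.746 between the congenic strains. These contrasts share no library, but any other difference between the diet groups that the strains have in common would also give such agreement. In the sample titles the high salt numbers lie above all normal salt numbers, except for S2Bb high salt replicates 2 and 3. Salt and a difference between such sets of animals cannot be told apart here. With the clock components as covariates the correlations were 0.692, 0.599 and 0.742. The difference in response between strains is tested by the interaction.

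**Figure D2:**
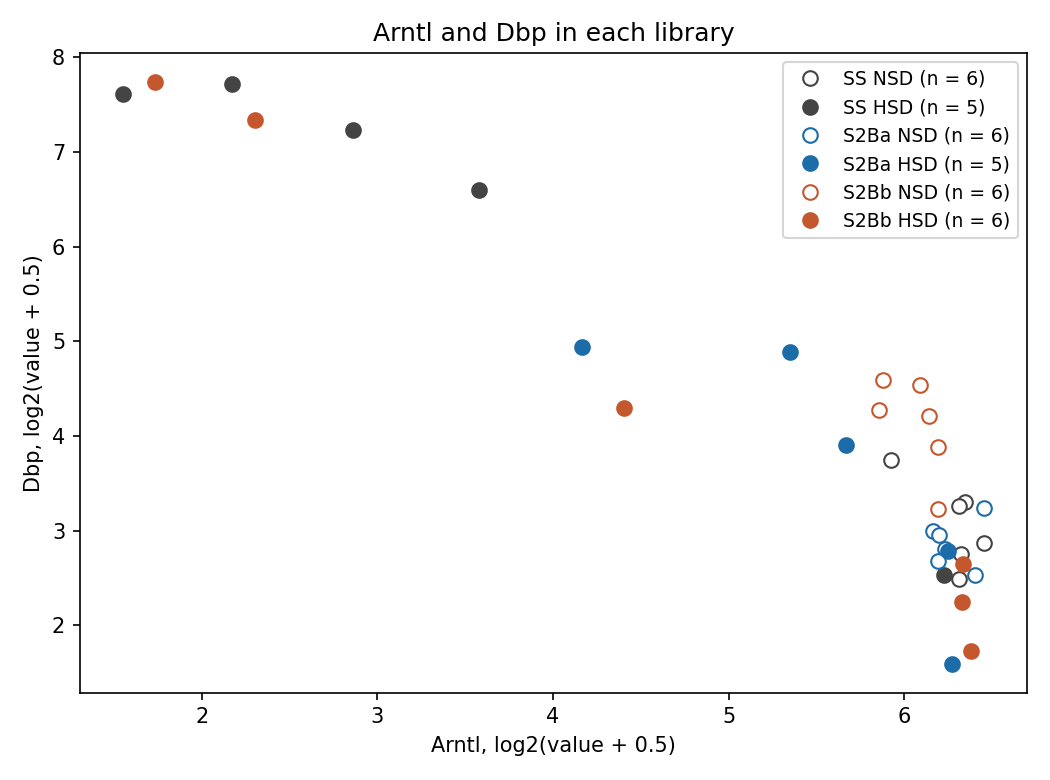
Arntl (horizontal axis) against Dbp (vertical axis) in each of the 34 libraries, both as log2(value + 0.5), with open points for normal salt (NSD) and filled points for high salt (HSD). The normal salt libraries lie together at high Arntl, while high salt libraries of each strain spread along a descending band.

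Between S2Ba and SS on normal salt, which differ in the distal part of chromosome 2, several genes of that chromosome differed. Slc9b1, of the sodium-proton exchanger family, was at 1.69 ± 0.204 in S2Ba and 4.74 ± 1.17 in SS (n = 6 each), and Enpep was at 16.01 ± 4.40 and 49.9 ± 4.16, a log2 fold change of -1.65 (SE 0.22). Ccdc109b, a subunit of the mitochondrial calcium uniporter, was higher in S2Ba, at 5.03 ± 1.03 against 1.73 ± 0.409, and so was Slc39a8, a metal ion transporter, at 8.30 ± 1.08 against 4.26 ± 0.461. Adh7, an alcohol dehydrogenase, had 0 reads in all 6 S2Ba libraries and 123 reads in the 6 SS libraries, at least 43.5-fold lower in S2Ba against the floor of 3 counts over the group. Meis1, a homeobox transcription factor on chromosome 14, was higher in S2Ba, at 131 ± 15.3 against 77.0 ± 13.6. The adjusted p from limma was 3.52e-06 for Slc9b1 and Meis1, 3.9e-05 for Enpep, 0.000522 for Ccdc109b, 0.00177 for Slc39a8 and 3.62e-05 for Adh7, and for each of these 6 genes the libraries of the strains did not overlap (0.216% for a gene not chosen for its difference). Hs2st1, a sulfotransferase of heparan sulfate, was at 24.02 ± 2.92 and 22.6 ± 3.77 (log2 fold change 0.09, 95% interval -0.15 to 0.33, adjusted p = 0.763).

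Of the 28 lists, only that of renin-angiotensin and endothelin held a called gene between S2Ba and SS on normal salt in limma, which was Enpep, and 2 of its 16 genes were called when adjusted over the list alone. Of 25 oxidative phosphorylation genes 8 were higher in S2Ba when adjusted over the list alone, 11 at an unadjusted p under 0.05 and 0 when adjusted over all genes (camera adjusted p = 1.12e-09, and adjusted p = 0.709 with an estimated correlation). Of 25 interferon response genes 1 was higher when adjusted over the list alone (camera adjusted p = 0.000133, and adjusted p = 0.709 with an estimated correlation). Antigen presentation and cell cycle genes passed camera on the higher side and endothelial genes on the lower side, each at an adjusted p of 0.0159 (adjusted p = 0.709, 0.814 and 0.735 with an estimated correlation), with 2 of 17, 2 of 24 and 4 of 16 genes at an unadjusted p under 0.05 in limma and 0 called. In total 36 genes were called, 16 higher and 20 lower in S2Ba, and 1960 had an unadjusted p under 0.05. The balance of directions depended on the setting, with 107 higher and 49 lower in DESeq2, 206 and 102 in limma voom and 185 and 121 without SS normal salt replicate 3. The count was 156 in DESeq2, 7 with adipocyte and muscle scores as covariates, and 79 without S2Ba normal salt replicate 1. Without SS normal salt replicates 1 to 6 in turn it was 20, 17, 306, 9, 11 and 12, and without S2Ba normal salt replicates 1 to 6 it was 79, 81, 20, 158, 17 and 13.

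On high salt Ccdc109b was at 6.65 ± 0.970 in S2Ba and 1.32 ± 0.397 in SS (n = 5 each), 4.00-fold higher, and Ddah1, which degrades an inhibitor of nitric oxide synthase, was at 12.3 ± 4.66 and 36.2 ± 4.60, 3.01-fold lower. Slc9b1 was lower and Slc39a8 and Meis1 were higher in S2Ba, as on normal salt. Of 17 antigen presentation genes 5 were higher and 0 lower, with 6 adjusted over the list alone (camera adjusted p = 4.1e-07, and adjusted p = 0.155 with an estimated correlation). RT1-Db1, a chain of the rat class II histocompatibility complex, was at 41.7 ± 9.91 against 18.7 ± 4.57, and Cd74, the invariant chain of that complex, at 196 ± 58.1 against 98.2 ± 27.7. RT1 genes are close relatives of each other, so their values are uncertain where reads were shared between copies. Edn1 was at 9.06 ± 3.39 against 2.71 ± 0.910, and the sulfotransferase gene Hs2st1 at 31.4 ± 6.44 against 20.04 ± 2.26. The adjusted p from limma was 2.08e-06 for Ccdc109b, 6.26e-05 for Ddah1, 0.000596 for RT1-Db1, 0.00454 for Cd74, 0.00509 for Edn1 and 0.012 for Hs2st1.

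The calls of Edn1 (adjusted p = 0.161) and Hs2st1 (adjusted p = 0.0866) were lost with the clock components as covariates, and that of Hs2st1 also without S2Ba high salt replicate 4 (adjusted p = 0.0562). On high salt the mean of the first clock component was 5.26 in SS and -0.80 in S2Ba, so these covariates can also take out strain differences. The loss does not show that the calls depend on the clock. Enpep, at 54.3 ± 19.03 in S2Ba and 66.6 ± 5.98 in SS, was not called on high salt (log2 fold change -0.36, 95% interval -0.84 to 0.13, adjusted p = 0.465), and with surrogate variables its adjusted p was 0.0396. Of 19 macrophage genes 1 was higher, with 4 adjusted over the list alone (camera adjusted p = 1.16e-07, and adjusted p = 0.34 with an estimated correlation), of 25 inflammatory mediators and adhesion genes 2 were higher, with 4 adjusted over the list alone (camera adjusted p = 0.00565, and adjusted p = 0.34 with an estimated correlation), and of 17 heparan sulfate genes 2 were higher, with 2 adjusted over the list alone. Hs2st1 is among the latter and was picked by the study on these samples, so the count is not independent evidence. The skeletal muscle score was lower in S2Ba by a log2 difference of -0.39 (8 measured genes, adjusted p = 0.0344, exact permutation test), and with medians over the members the adjusted p was 0.103. Scores of B and plasma cells and of cardiac muscle differed by -0.61 and -0.68 (adjusted p = 0.0344 each, and 0.0516 each when adjusted among the medians of the lists) but have 2 measured genes each and rest on 1, Blk (-1.47, with Cd22 at 0.24) and Actc1 (-1.45, with Myl4 at 0.10). Of 17 clock genes 0 were higher and 2 lower, with 14 adjusted over the list alone (camera adjusted p = 0.00216, and adjusted p = 0.155 with an estimated correlation).

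In all 233 genes were called between S2Ba and SS on high salt, 102 higher and 131 lower, and 65 differed at least 2-fold. The direction with more calls turned under upper quartile scaling. With the clock components as covariates the count was 16, and with adipocyte and muscle scores it was 27. Without SS high salt replicate 2, 4, 5 or 6 it was 95, 61, 130 or 129, and without S2Ba high salt replicate 3, 4, 5 or 6 it was 98, 47, 448 or 129.

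S2Bb and SS differ in the middle of chromosome 2, and on normal salt they differed at several genes of that chromosome. Kcnab1, a subunit of voltage-gated potassium channels, was at 49.7 ± 5.44 in S2Bb and 4.86 ± 1.60 in SS (n = 6 each), a log2 fold change of 3.28 (SE 0.19). Nlgn1, a synaptic adhesion molecule, was at 0.0745 ± 0.0475, with 6 reads in the S2Bb group, against 4.05 ± 1.30. Agtr1b, a type 1 receptor of angiotensin II, was at 2.64 ± 0.905 against 8.40 ± 2.90, and Lxn, a carboxypeptidase inhibitor, at 8.03 ± 0.804 against 21.3 ± 7.30. Ryr3, a calcium release channel encoded on chromosome 3, was at 9.56 ± 2.65 against 25.7 ± 5.91. Agtr1b has a close relative, Agtr1a, with which reads could have been shared. The adjusted p from limma was 1.49e-14 for Kcnab1, 8.15e-13 for Nlgn1, 2.21e-05 for Agtr1b, 9.35e-06 for Lxn and 0.00028 for Ryr3, and the libraries of the strains did not overlap for these 5 genes (0.216% for a gene not chosen for its difference).

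Of 25 potassium and calcium channel genes 0 were higher and 3 lower in S2Bb on normal salt, with 6 adjusted over the list alone. Enpep (log2 fold change 0.08, adjusted p = 0.922) and Hs2st1 (log2 fold change 0.10, adjusted p = 0.782) were not called. In total 194 genes were called, 64 higher and 130 lower, and the direction with more calls depended on the setting. With the clock components as covariates the count was 68, and without SS normal salt replicates 1 and 2 it was 118. Without SS normal salt replicate 1, 3 or 4 it was 103, 347 or 102, and without S2Bb normal salt replicate 5 or 6 it was 127 or 102.

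On high salt Kcnab1 was at 44.0 ± 9.997 in S2Bb (n = 6) and 2.95 ± 0.728 in SS (n = 5), Nlgn1 at 0.143 ± 0.136 and 5.91 ± 1.18, and Agtr1b at 2.62 ± 0.679 and 15.5 ± 3.99. Bbs12, a chaperonin-like gene of the primary cilium, was higher in S2Bb, at 11.7 ± 1.42 against 5.97 ± 0.7095. The log2 fold changes were 3.68 (SE 0.19), -3.32 (SE 0.20), -2.35 (SE 0.21) and 0.92 (SE 0.14), with adjusted p of 1.85e-15, 9.21e-14, 3.43e-09 and 0.000266 in limma, and the groups did not overlap for these 4 genes (0.433% for a gene not chosen for its difference). Of 17 antigen presentation genes 1 was higher, with 8 adjusted over the list alone (camera adjusted p = 2.4e-07, and adjusted p = 0.378 with an estimated correlation), and the 19 macrophage genes, of which 6 had an unadjusted p under 0.05 in limma and 0 were called, passed camera on the higher side (adjusted p = 1.74e-08, and adjusted p = 0.378 with an estimated correlation). Scores of skeletal muscle, cardiac muscle and mesothelium differed by -0.24, -0.54 and -0.36 on the log2 scale and that of chondrocytes by 0.28 (adjusted p = 0.0375, 0.0281, 0.0422 and 0.0375, exact permutation test), and with medians the adjusted p was 0.0659 for skeletal muscle and 0.089 for chondrocytes. The cardiac score has 2 measured genes and rests on Actc1 (-1.13, not called, with Myl4 at 0.05). Enpep (log2 fold change 0.32, adjusted p = 0.749) and Hs2st1 (log2 fold change 0.29, adjusted p = 0.489) were not called.

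The count of called genes between S2Bb and SS on high salt was 36, of which 12 were higher and 24 lower, with 1181 at an unadjusted p under 0.05. It was 141 in limma voom and 17 with the clock components as covariates. Without SS high salt replicate 2 or 4 it was 19 or 16, and without S2Bb high salt replicate 1 or 5 it was 22 for each.

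**Figure D3:**
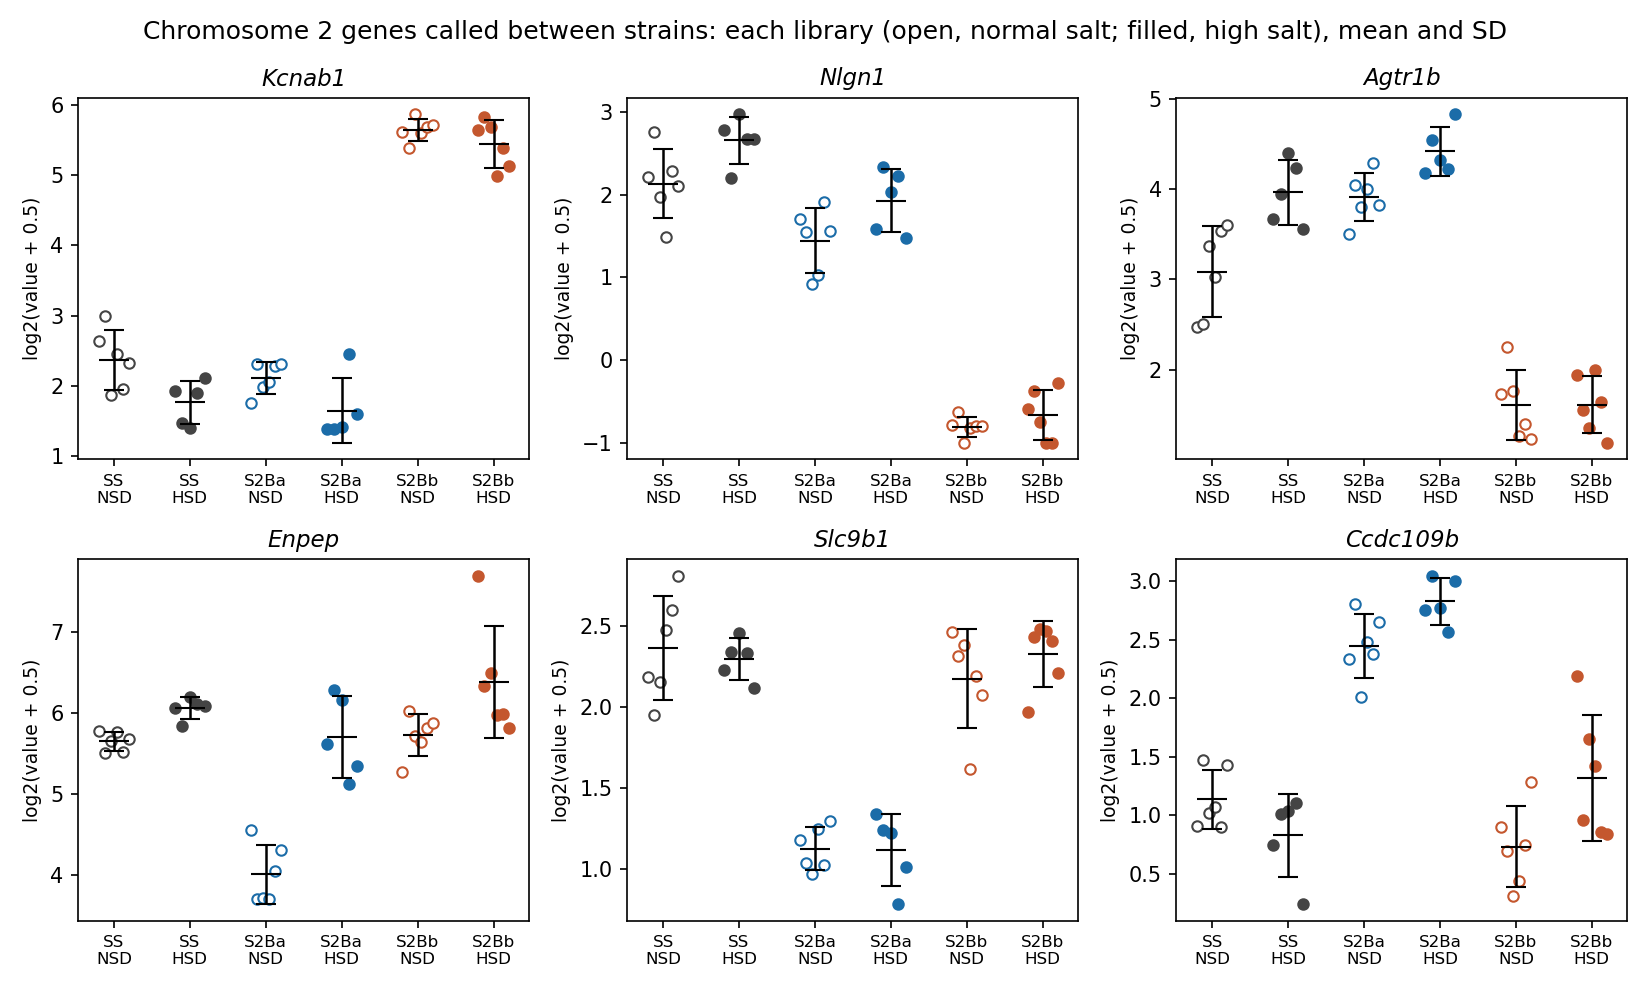
Each library's log2(value + 0.5) for 6 chromosome 2 genes called between strains (vertical axes, 1 panel per gene), by strain and diet (horizontal axes, NSD normal salt and HSD high salt), with bars for the mean and SD. Kcnab1 is higher and Nlgn1 and Agtr1b are lower in both S2Bb groups, while Slc9b1 is lower and Ccdc109b higher in both S2Ba groups and Enpep is lowest in S2Ba on normal salt.

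Chromosome 2 holds 816 of the 12239 tested genes with a known chromosome, or 6.67%. It held 13 of the 34 placed calls between S2Ba and SS on normal salt (odds ratio 8.79, 95% interval 4.03 to 18.5, adjusted p = 1.56e-07, Fisher's exact test) and 30 of 223 on high salt (odds ratio 2.22, 1.45 to 3.30, adjusted p = 0.000206). For S2Bb it held 47 of 181 on normal salt (odds ratio 5.15, 3.58 to 7.29, adjusted p = 8.04e-16) and 17 of 29 on high salt (odds ratio 20.2, 9.06 to 46.6, adjusted p = 4.2e-13). Genes of 1 segment are inherited together and are not independent.

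Both diets called 7 genes between S2Ba and SS in the same direction, against 0.121 higher and 0.194 lower for independent lists. They were Adh7, Ccdc109b, Ddah1, Ddi2, Meis1, Slc39a8 and Slc9b1, of which 5 lie on chromosome 2. For S2Bb 14 genes were shared, 4 higher and 10 lower, against 0.057 and 0.232 for independent lists, of which 10 lie on chromosome 2, Kcnab1, Nlgn1 and Agtr1b among them, and 4 have no chromosome in the table used.

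**Figure D4:**
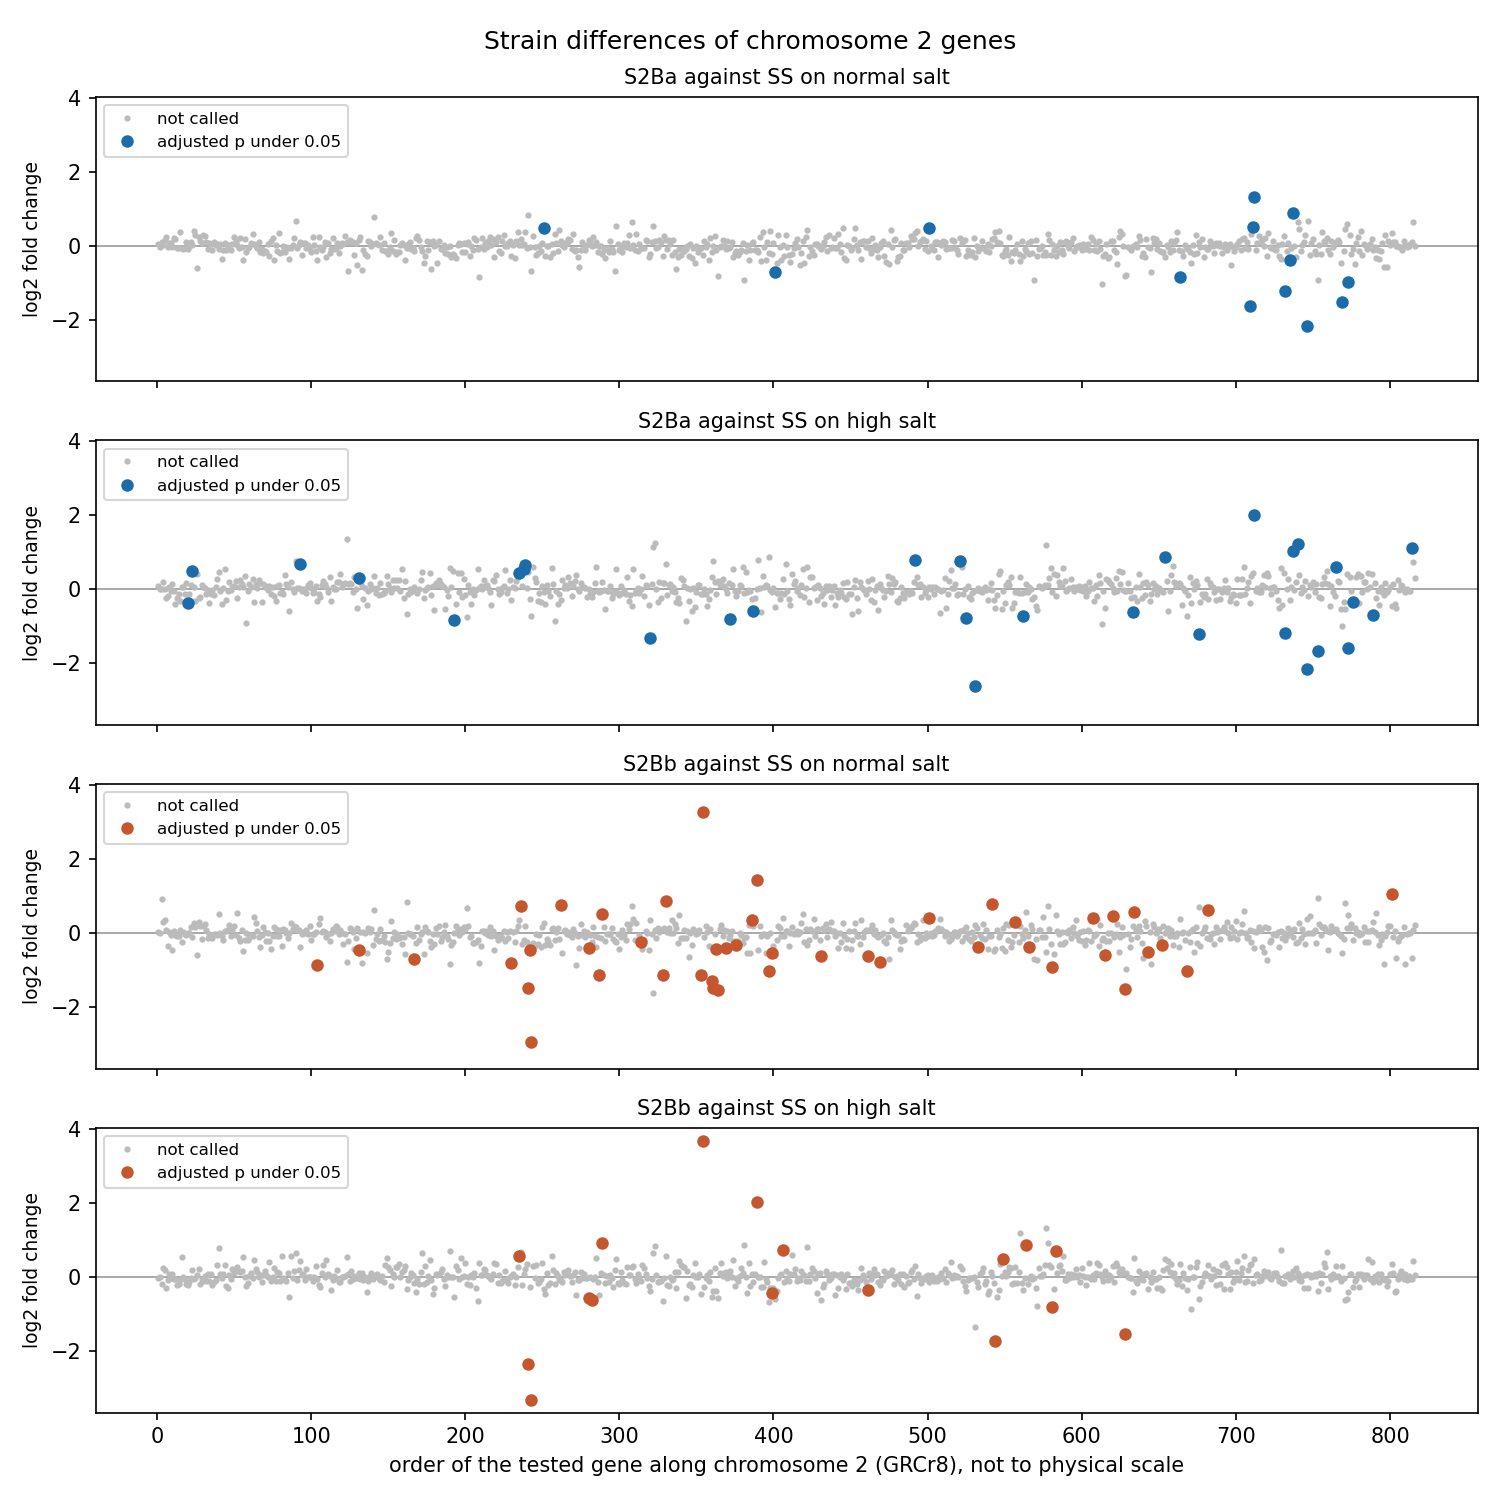
Log2 fold change of each congenic strain against SS (vertical axis, 1 panel per strain and diet) for the 816 tested genes of chromosome 2, in the order they have along GRCr8 (horizontal axis, not to physical scale). Coloured points are genes with an adjusted p under 0.05 and grey points the rest. Genes called in both diets lie at positions 712 to 773 for S2Ba and 241 to 628 for S2Bb.

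The congenic strains were compared with the same SS libraries, so some overlap arises without any effect. On normal salt 4 genes were called in both strains with the same direction, Amigo2, Ddi2, Fam160a1 and Psmb4, and on high salt 8, among them Myo19, a mitochondrial myosin, RT1-Db1 and Ifitm3, an interferon-induced membrane protein, all of them chosen after their values were seen. Simulations of unchanged groups gave a median of 0 shared genes, and independent lists gave 0.076 higher and 0.193 lower on normal salt and 0.0908 and 0.233 on high salt. With the SS libraries split between the strains the median number shared was 0 on both diets, with up to 4 on normal salt and up to 1 on high salt. The split left 3 SS libraries for each strain on normal salt, and 3 and 2 on high salt. Calls are also lost through fewer libraries, so the drop does not show that the shared libraries made the overlap. Across genes the log2 fold changes of the strains correlated at 0.363 on normal salt (0.504 simulated), with a covariance of 0.0204 against 0.0174 simulated (95% of simulations 0.00581 to 0.0337), and at 0.586 on high salt (0.505 simulated), with a covariance of 0.0396 against 0.0201 (0.0086 to 0.038). The covariance thus lay within that range on normal salt and just above it on high salt, at differences of 0.00309 and 0.0195 from the simulated mean. The simulations shuffled the residuals of all 34 libraries over the groups. Their range follows the pooled spread and not that of the shared SS libraries, so it decides neither case. With the SS libraries split the median correlation was 0.0454 on normal salt (-0.28 to 0.234) and 0.345 on high salt (0.221 to 0.391).

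Whether salt acted differently in a congenic strain than in SS was tested by the interaction. For S2Bb limma called 23 genes, 10 higher and 13 lower. Blk fell with salt in S2Bb by a log2 fold change of -2.06 and stood at -0.21 in SS, and Kcnq3 stood at 2.92 in S2Bb and 1.07 in SS. Ppm1l, a protein phosphatase gene on chromosome 2, stood at 0.32 in S2Bb and -0.21 in SS. The differences were -1.85 (SE 0.37), 1.85 (SE 0.40) and 0.52 (SE 0.090), with adjusted p of 0.0288, 0.0418 and 0.0212 in limma. No gene was called with the clock components as covariates, without SS normal salt replicates 1 and 2 together, or without replicate 1 or replicate 4 of that group, while limma voom called 355 genes and DESeq2 called 124. Without SS normal salt replicate 2 or 3 the count was 3 or 102, without SS high salt replicate 4, 5 or 6 it was 2, 1 or 1, without S2Bb normal salt replicate 1, 2, 4, 5 or 6 it was 2, 41, 2, 5 or 1, and without S2Bb high salt replicate 1, 3, 4, 5 or 6 it was 2, 15, 2, 7 or 66.

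For S2Ba, limma called 0 interaction genes, with 1308 at an unadjusted p under 0.05, while edgeR called 1, DESeq2 10 and limma voom 12. The smallest adjusted p was 0.0679, for Myo19, whose log2 fold change with salt was 0.90 in SS and -0.10 in S2Ba. Enpep changed with salt by 1.70 in S2Ba and stood at 0.41 in SS, a difference of 1.29 (SE 0.32, adjusted p = 0.252), and for Edn1 the difference was 1.63 (SE 0.40, adjusted p = 0.252). For Hs2st1 it was 0.52 (SE 0.18, adjusted p = 0.343).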

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

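Of the tests and values given here, the ratio of the spread of the clock component between diets, the smooth muscle scores of libraries with displaced clock genes and the separate correlations of Usp2 and Wee1 were chosen only after the result was seen.

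Clock genes spread widely between animals of the same high salt group: the first principal component of the clock list stood at 5.26 ± 4.74 in SS (range -2.84 to 8.58, n = 5), at -0.80 ± 2.70 in S2Ba (n = 5) and at 1.59 ± 5.39 in S2Bb (n = 6), while its SD in the normal salt groups was 0.831 to 0.989. The SD within groups was 4.94 times as large on high as on normal salt (4.51 against 0.913), which describes the spread and tests no explanation of it. Animals whose clocks stood at different phases, for example through different hours of collection, are a candidate explanation, and the labels give no hour. Within high salt groups, libraries with neighbouring numbers in their sample titles stood close on the component. S2Bb replicates 2 and 3 were at -2.68 and -2.42, and 5 and 6 at 7.99 and 8.46. SS replicates 4 to 6 were at 8.58, 6.95 and 5.10, and S2Ba replicates 5 and 6 at -3.11 and -3.90. Whether these numbers mark sets of animals is not given. The permutation p-values below take the libraries as exchangeable and do not cover such sets. The mean of Usp2 and Wee1, rhythmic genes outside the list, followed the component over the 16 high salt libraries (r = 0.716, permutation p = 0.0018, Spearman's rho 0.709, permutation p = 0.0029, and r = 0.657 without the 2 libraries farthest from the median). Apart, Wee1 correlated at 0.806 (permutation p = 0.00022) and Usp2 at 0.231 (permutation p = 0.397), so this explanation stays open. Dilution by tissue poor in smooth muscle was argued against: in the 9 high salt libraries whose component lay above all normal salt libraries, Arntl was lower than the normal salt mean of its strain by 0.92 to 4.73 on the log2 scale, while the smooth muscle score differed from its mean by -0.015 to 0.222 (SD on normal salt 0.0649 to 0.173). Tissue as rich in smooth muscle genes as aorta stays open, with the highest correlation of a cell type score at 0.653 for B and plasma cells (2 genes, adjusted p = 0.0944, permutation test, 13 scores), and a difference between strains in the response of the clock was not tested apart from the hour.

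In 25 of 265 groups of values 1 library stood far from the rest of its group, where chance gives about 1 in 20 groups, or 13.2. Among normal salt SS libraries, replicate 6 had a cardiac muscle score of 0.821 (others -0.054 to 0.198), replicate 3 a chondrocyte score of 4.36 (others 2.09 to 2.72) and replicate 4 a first clock component of -0.39 (others -3.12 to -2.15). For S2Ba, replicate 1 on normal salt had a mesothelial score of 2.96 (others 1.61 to 2.04), replicate 5 a chondrocyte score of 1.79 (others 2.27 to 2.40), and replicate 1 on high salt had about 16500 detected genes (others about 16200 to 16300). For S2Bb on normal salt, replicate 2 had a macrophage score of 3.82 (others 4.12 to 4.20) and a chondrocyte score of 3.21 (others 2.08 to 2.39), replicate 1 a smooth muscle score of 9.95 (others 9.71 to 9.78) and replicate 5 an erythroid score of 5.80 (others 3.53 to 4.03). On high salt S2Bb replicate 6 had an adipocyte score of 4.86 (others 3.43 to 3.95) and a Schwann and neuronal score of 2.18 (others 1.45 to 1.71).

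Single genes with a library apart were Arntl, at 60.1 in SS normal salt replicate 4 (others 78.8 to 87.2), Hs2st1, at 24.1 in SS high salt replicate 2 (others 18.8 to 19.2), and Slco1a4, at 2.51 in that same library (others 3.78 to 4.21). Ryr3 was at 14.2 in SS normal salt replicate 3 (others 25.7 to 31) and at 4.18 in S2Bb normal salt replicate 2 (others 10.3 to 11). Fam174b was at 1.15 in S2Bb normal salt replicate 3 (others 0.591 to 0.659), and Ntn4 at 39.3 in S2Bb high salt replicate 1 (others 30.8 to 33.1). In that last library Pln was at 957 (others 499 to 617) and Krt18 at 0.832 (others 2.80 to 3.40). In SS high salt replicate 1 Pln was at 393 (others 565 to 585) and Dbp at 5.28 (others 96.5 to about 210). Mki67 was at 12.7 in S2Bb normal salt replicate 1 (others 5.23 to 6.80) and at 18 in S2Bb high salt replicate 6 (others 31.5 to 42.3).

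The response to salt differed between S2Bb and SS for 23 genes in limma. The difference was 0.52 for the phosphatase gene Ppm1l, -1.85 for Blk, 1.85 for Kcnq3, 1.34 for Fam174b, a membrane protein gene, 0.91 for Ntn4, which encodes netrin 4, and -1.82 for Slco1a4, an organic anion transporter gene. Of the 23 genes, 20 were called for salt in S2Bb and 7 for salt in SS, 15 differed between the strains on normal salt and 3 on high salt, and 13 had opposite signs of the salt effect in the strains. All 23 had the same sign in the S2Ba interaction, which is taken against the same SS libraries, so the differences are not shown to be particular to S2Bb.

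Other splits of the same libraries into groups of the real sizes were drawn, 100 for each contrast, the real one included. For salt in SS 1 split, the real one, gave as many calls (1129, highest other 214). The same held for salt in S2Ba (2042, highest other 1693, a split that left 9 of the 11 libraries in their own group) and in S2Bb (2974, highest other 357). It also held for S2Ba against SS on high salt (233, highest other 27) and S2Bb against SS on high salt (36, highest other 21). This argues against chance there, although 100 splits cannot show a share below 1 in 100. For S2Bb against SS on normal salt 2 splits gave as many (194, highest other 462, a split that left 10 of the 12 libraries in their own group). Chance is argued against less strongly for that contrast and is not excluded, because another split gave more calls than the real one. For the S2Bb interaction 2 splits gave as many too (23, highest other 49). The splits of an interaction exchanged strain labels within each diet. They break the strain difference along with the interaction, so they do not decide on the interaction. No adjustment was made over the 9 contrasts. For S2Ba against SS on normal salt 5 splits gave as many calls as the real one (36, highest other 2537), so chance cannot be excluded for that count. The split with 2537 calls put SS replicates 2 and 3 with S2Ba replicates 2, 3, 5 and 6, and points to a structure of the samples other than strain. For the S2Ba interaction, with 0 calls in limma and 1308 genes at an unadjusted p under 0.05 (1 call in edgeR, 10 in DESeq2 and 12 in limma voom), all 100 splits give at least as many calls by construction (highest other 192), so they decide nothing there.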

How the results depend on the processing

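The edgeR test on recovered reads, the omission of single libraries, of SS normal salt replicates 1 and 2 together and of S2Ba normal salt replicate 1, and the clock components as covariates were chosen only after the results were seen. Scaling by relative log expression or the upper quartile, pseudocounts of 0.1 and 1, and a mean of at least 1 left each count of called genes within 1.5 times its value, with that of the S2Ba interaction at 0 throughout. The direction with more calls turned under at least 1 setting in each contrast with calls but S2Bb against SS on high salt, where 17 higher and 17 lower without SS high salt replicate 1 was the nearest: for salt in SS, with 598 higher and 531 lower, it was 232 and 329 at 1.5-fold, and for S2Ba against SS on high salt, with 102 and 131, it was 104 and 96 under upper quartile scaling. Chromosome 2 held more than its share of strain calls under each alternative tried for it. Counts from edgeR were 1063, 2187 and 3046 for salt in SS, S2Ba and S2Bb, 32 and 226 for S2Ba against SS on normal and high salt, 217 and 38 for S2Bb, and 1 and 20 for the interactions. Where counts moved, a stricter threshold passes fewer genes by construction. In the other cases the cause was not tested. No paired analysis was possible because the replicate numbers follow the order of the records and pair no samples. Depth limits the genes with low values, of which 12631 were not tested.

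For salt in SS (1129 calls) the count was 281 at an adjusted p under 0.01, 561 with at least a 1.5-fold change, 2788 in limma voom, 723 with no filter, 512 with surrogate variables, 701 with adipocyte and muscle scores and 510 with clock components. Omitting 1 library gave 519 to 1709, lowest without SS high salt replicate 5 and highest without SS normal salt replicate 3. For salt in S2Ba (2042) it was 931 under 0.01, 1071 at 1.5-fold, 1093 with only the compared groups and 923 with surrogate variables, and 1508 to 2409 without 1 library. For salt in S2Bb (2974) it was 1714 under 0.01, 1244 at 1.5-fold and 1458 with clock components, and 2420 to 3022 without 1 library.

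For S2Ba against SS on normal salt (36) the count was 9 under 0.01, 19 at 1.5-fold, 156 in DESeq2, 308 in limma voom, 6 with only the compared groups, 7 with adipocyte and muscle scores, 20 without SS normal salt replicates 1 and 2 and 79 without S2Ba normal salt replicate 1. Omitting 1 library gave 9 (SS normal salt replicate 4) to 306 (SS normal salt replicate 3). For S2Ba against SS on high salt (233) it was 35 under 0.01, 494 in DESeq2, 934 in limma voom, 103 with no filter, 360 with only the compared groups, 103 with surrogate variables, 27 with adipocyte and muscle scores and 16 with clock components, and 47 (without S2Ba high salt replicate 4) to 448 (without S2Ba high salt replicate 5). For S2Bb against SS on normal salt (194) it was 60 under 0.01, 108 at 1.5-fold, 366 in DESeq2, 534 in limma voom, 477 with surrogate variables, 68 with clock components and 118 without SS normal salt replicates 1 and 2, and 102 (without SS normal salt replicate 4 or S2Bb normal salt replicate 6) to 347 (without SS normal salt replicate 3). For S2Bb against SS on high salt (36) it was 16 under 0.01, 70 in DESeq2, 141 in limma voom, 23 with adipocyte and muscle scores and 17 with clock components, and 16 (without SS high salt replicate 4) to 51 without 1 library.

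The salt by S2Ba interaction (0 calls in limma, with 1308 genes at an unadjusted p under 0.05) gave 10 in DESeq2, 12 in limma voom, 1 in edgeR and 3 without S2Ba normal salt replicate 1, and 0 to 3 without 1 library. The salt by S2Bb interaction (23) gave 124 in DESeq2, 355 in limma voom, 1 with no filter, and 0 under 0.01, with clock components and without SS normal salt replicates 1 and 2, and 0 (SS normal salt replicate 1 or 4) to 102 (SS normal salt replicate 3) without 1 library. The overlap of S2Bb strain calls between diets went from 14 to 9 genes with clock components. The overlap of calls between congenic strains went from 4 to 9 on normal salt and from 8 to 3 on high salt with no filter. It went to a median of 0 on both diets with the SS libraries split, which also leaves fewer SS libraries in each comparison. Of 252 list tests 42 passed camera with the preset correlation and 0 with an estimated one. Of 91 marker score tests 9 passed with the mean and 5 with the median over members, 4 of them with both. The mesothelial score for salt in S2Ba passed with the median alone (adjusted p = 0.0281, against 0.112 with the mean, exact permutation test).

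Among 326 values of named genes, calls were lost for 108 with clock components, 85 with surrogate variables, 64 with no filter, 59 with adipocyte and muscle scores, 51 with only the compared groups, 15 in edgeR, 14 in limma voom, 11 with upper quartile and 5 with relative log expression scaling, 5 and 3 with pseudocounts of 1 and 0.1, and 2 in DESeq2. Calls were lost for 38 of 115 without SS normal salt replicates 1 and 2, for 13 of 90 without S2Ba normal salt replicate 1, and in 699 of 3875 cases without 1 library. The value that changed direction was Cry2, salt in S2Bb, from 0.37 to -0.022 with clock components. Cry2 is a member of the clock list, so these components take out much of its change by construction, as for the other clock genes. The components also differ between groups, so they can take out part of a group difference of any gene.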

Other observations

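The thinning of libraries to equal depth and both tests on the order and direction of chromosome 2 genes were chosen only after the result was seen.

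Some gene groups of the salt comparisons have not been described so far. Fam132a fell in S2Bb from 25.8 ± 5.94 to 3.54 ± 2.38 (n = 6 each, adjusted p = 5.35e-07 in limma), and the mesothelial keratin gene Krt18 fell from 10.8 ± 3.37 to 2.76 ± 0.968 (adjusted p = 2.61e-05). Of 17 immediate early genes 1 rose and 2 fell in S2Bb, with 3 adjusted over the list alone: Junb rose from 38.2 ± 20.1 to 103 ± 16.5 and Jun, a partner of the same transcription factor complex, fell from 570 ± 300 to 142 ± 109. Ryr3 rose in S2Bb from 9.56 ± 2.65 to 23.4 ± 6.48. Of 17 antigen presentation genes 3 rose and 1 fell with salt in S2Bb, with 6 adjusted over the list alone, and of 25 oxidative phosphorylation genes 0 rose and 4 fell, with 2 adjusted over the list alone. The numbers of called immediate early, antigen presentation and oxidative phosphorylation genes do not stand out from the 22.1% of all tested genes called there. Fatty acid synthesis genes (18 measured, 5 at an unadjusted p under 0.05 and 0 called in limma) and adipocyte genes (20 measured, 4 and 0) passed camera on the lower side for salt in SS at adjusted p of 0.00688 and 0.0421, with an adjusted p = 0.999 for each with an estimated correlation. Of 7 Schwann and neuronal genes 0 rose and 2 fell with salt in SS, with 3 adjusted over the list alone. Of 9 chondrocyte genes 2 rose with salt in S2Ba, with 2 adjusted over the list alone, and of 6 mast cell genes 1 rose there, with 1 adjusted over the list alone.

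Several lists of blood and muscle cell markers are short. Of 8 skeletal muscle genes 1 was called for salt in SS, 2 in S2Ba and 2 in S2Bb. The 8 measured T and NK cell genes and the 18 fatty acid synthesis genes held 0 called genes in each of the 9 contrasts in limma, and 0 when adjusted over the list alone, with at most 1 and 5 genes at an unadjusted p under 0.05 in a contrast. Of 2 measured B and plasma cell genes 1, Blk, fell with salt in S2Ba and in S2Bb, with 1 adjusted over the list alone, and of 2 measured cardiac muscle genes 1 rose with salt in SS and 1 in S2Bb, with 1 and 2 adjusted over the list alone. Of 3 mesothelial genes 0 rose and 2 fell with salt in S2Ba and in S2Bb, with 2 adjusted over the list alone. Of 7 erythroid genes 1 fell with salt in S2Ba, with 1 adjusted over the list alone, and the erythroid list passed camera on the lower side for S2Bb against SS on high salt (adjusted p = 0.034, and adjusted p = 0.434 with an estimated correlation). Of 8 skeletal muscle genes 0 were higher and 2 lower in S2Ba than in SS on high salt, with 3 adjusted over the list alone. The gene with the smallest adjusted p between S2Bb and SS was the unnamed gene AABR07012585.3, chosen after its values were seen, which was at 33.5 ± 4.08 in S2Bb and 0.381 ± 0.222 in SS on normal salt and has no chromosome in the table used.

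Other lists passed camera with the preset correlation, and none of them with an estimated one. Oxidative phosphorylation genes lay on the lower side for salt in S2Ba (adjusted p = 0.0343, 1 of 25 fell) and on the higher side for S2Bb against SS on normal salt (0.00269, 2 of 25 at an unadjusted p under 0.05 in limma, 0 called), where Schwann and neuronal genes lay on the lower side (0.0407, 3 of 7, 0 called). For S2Ba against SS on high salt, cell cycle (2.58e-06, 1 of 24 higher) and oxidant and antioxidant genes (0.00927, 6 of 24 at an unadjusted p under 0.05, 0 called) lay on the higher side, as did cell cycle (0.000174, 1 of 24, 0 called) and endothelial genes (0.00325, 2 of 16, 0 called) for S2Bb on high salt. In all 5 lists passed on the higher side and 2 on the lower side for S2Ba against SS on high salt, not all of them named here. In the S2Ba interaction macrophage (3.92e-06), endothelial (0.00765), antigen presentation and chondrocyte genes (0.0146 each) lay on the higher side and oxidative phosphorylation (0.000118) and mesothelial genes (0.0195) on the lower side. In the S2Bb interaction macrophage (0.00256), endothelial and cell cycle (0.00412 each) and antigen presentation genes (0.0412) lay on the higher side and erythroid (0.00412), oxidative phosphorylation (0.0106) and mesothelial genes (0.039) on the lower side.

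SS normal salt replicates 1 and 2 held reads of many genes seen in no other library, 1276 of them in both. Deeper sequencing was argued against. Replicate 2 was itself the smallest library (8753735 reads), so thinning all libraries to the smallest left its 22207 detected genes unchanged. Replicate 1 (10645605 reads) still had 20310 after thinning (highest other 16476). The 10 most abundant of these genes held 3.78% of their reads, which argues against a tissue with abundant genes seen in no other library. Genes with any read in another library were left out of this set, whose highest count in 1 library was 30 reads. A tissue whose abundant genes leave traces in the other libraries is therefore not argued against. Genomic DNA is a candidate explanation that remains: 224 and 344 of 510 olfactory receptor genes were detected in these libraries, against 8 to 23 in the others, a ratio of at least 9.74. The labels name a DNA removal step for the RNA, and how completely it worked in these samples cannot be read from them.

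Strain calls gathered on chromosome 2, and the exchanged segments are a candidate explanation for part of them. Genes called in S2Ba alone (35) had a median position of 654 among the 816 tested genes of the chromosome and those called in S2Bb alone (50) a median of 393 (permutation p = 3e-05). The stretches were not separate: 15 of the 35 lay at position 700 or later and 16 at 200 to 699, where 47 of the 50 lay. The first range holds 117 tested genes and the second 500, so the calls of S2Ba alone were denser at 700 or later. Of the calls of S2Bb alone 1 lay there. Genes called on both diets lay at 712 to 773 for S2Ba and at 241 to 628 for S2Bb, without overlap. The segments stay open as an explanation, as the calls of S2Ba alone also reached the middle range. Better mapping of BN reads as the whole cause was argued against by the direction of the calls, since at most 47.1% of the called chromosome 2 genes were higher in the congenic strain. At an adjusted p under 0.01 it was 6 of 9 for S2Ba on high salt, 3 of 7 for S2Ba on normal salt, and 7 of 26 and 4 of 9 for S2Bb on normal and high salt. Reads of neighbouring or related genes that carry strain variants stay open, as does regulation by variants in the segment, because both move with the strain.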
